A study of Mus musculus with 2 samples.

How the data were processed

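Long-read RNA sequencing was performed on left cerebral cortex of female B6CASTF1/J mice, which are hybrids of the C57BL/6J and CAST/EiJ strains, at 2 months of age. There were 2 libraries, 1 per animal, named replicate 1 and replicate 2 after the biological replicate numbers in the labels. The names of the tissue samples point to 2 animals, while a free text field of the experiment repeats the name of 1 of them and both samples carry the same donor entry; the libraries were treated as 2 animals. They form 1 group, so the design holds no contrast between conditions. Per the labels, each library started from 2 µg of total RNA with ERCC spike-in mix 1 and Lexogen set 4 spike-ins (SIRVs and long SIRVs) added.

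The authors deposited, for each library, a table of whole-number read counts per transcript model and a file of the models' exons in mm10 coordinates. Per the read-me text beside the tables, reads were aligned to mm10 and assigned to models with GENCODE M21 as annotation. The deposited model tables carry TALON's field names, which sort each model into a class. A known model follows an annotated transcript. An incomplete splice match (ISM) follows only part of one, and a model new in catalogue (NIC) joins annotated splice sites in another combination. A model new not in catalogue (NNC) has at least 1 splice site outside the annotation. These are the classes as TALON defines them; some NIC chains here held a splice site outside the annotation used. Antisense, intergenic and genomic models lie opposite a gene, between genes, or within a gene without following its splicing. The sequencing platform's settings, the aligner, the versions of the tools and any filter on read quality are not given in the sources used here. The counts were not normalised before deposit, and each listed model has at least 1 read. Each count is a count of reads, so that intervals and limits given here cover counting error only.

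Reads of all models that the deposited count tables assign to an annotated gene were summed per gene and scaled to CPM, the count divided by the library's reads in annotated genes, in units of 1e-06. Spike-ins and antisense or intergenic models were left out of these totals. Replicate 1 had 686395 reads and replicate 2 had 858276 reads, of which 600391 and 746196 lay in annotated genes. At this depth a gene with a count of 0 has an upper limit, set at 3 reads, of 5.00 CPM in replicate 1 and 4.02 CPM in replicate 2. The agreement of the libraries was described by Pearson's r and Spearman's rho across genes of log2(CPM + 1), without a p-value because genes are not replicates. Genes with at least 20 reads over both libraries were compared by an exact two-sided binomial test on their reads, with the expected share taken from the library totals. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A call needed an adjusted p under 0.05 and at least a 2-fold difference in CPM. Log2 ratios are of CPM after 0.5 reads were added to each count. Such a test compares these 2 libraries, not conditions, and takes no account of variation between animals. On simulated counts for 9089 genes, the test called 83 of 100 genes changed 4-fold, 29 of 100 genes changed 2-fold and 6 of 8889 unchanged genes. These counts were drawn with counting error alone, as the test assumes, so the rates do not cover any spread beyond it. Genes simulated at exactly 2-fold lie on the limit for a call, which holds down their rate at any depth.

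The gene lists, 29 in number with 522 genes, were fixed before the data were examined, as were the rule for named genes, the tests and the alternatives. Exceptions are the tests on pairs of exons that replace each other, and the tests and 4 alternatives that the closing section names as chosen after the result was seen. They cover 7 cell classes of the cortex (excitatory and inhibitory neurons, astrocytes, oligodendrocytes, their precursors, microglia, endothelium with mural cells), meninges, choroid plexus, blood, striatum, hippocampus, and thalamus with hypothalamus. The other lists hold immediate early, circadian, glucocorticoid response, heat shock and interferon response genes, synaptic vesicle genes, glutamate receptors, GABA receptors, the postsynaptic density, large ion channels, mitochondrially encoded and nuclear oxidative phosphorylation genes, ribosomal proteins, long noncoding RNAs, splicing regulators and genes with known splice events. The median log2 ratio of each list with at least 3 tested members was placed among 10000 random lists of the same size, drawn from genes in the same of 20 bins of mean expression. Random lists were drawn gene by gene, while members of a list may vary together. The percentiles are therefore descriptive, and they were not adjusted over the lists. Calls are given over all genes tested and adjusted over the list alone.

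Isoforms were compared as intron chains, the ordered set of a model's introns, because model names need not match between the tables. The share of a gene's leading chain among its spliced reads was tested between the libraries by Fisher's exact test, two-sided, in genes with at least 50 such reads in each. Cassette exons were internal exons that some GENCODE transcripts hold and others skip. Percent spliced in is the share of inclusion reads among reads that join both neighbouring exons with or without the cassette exon, given for exons with at least 20 such reads in each library and averaged over the 2 animals. Microexons (3 to 27 nt) were compared with longer cassette exons by a two-sided permutation test with 100000 resamples of the difference in mean, and in the share of lengths divisible by 3 by Fisher's exact test. In simulated reads the mean absolute error of inclusion was 2.22 percentage points over 200 events with 200 reads each. The simulation held no loss in alignment, and its error does not apply to exons near the minimum of 20 reads. Shares of reads have Wilson 95% intervals, and exon shares have exact 95% intervals. New intron chains (NIC or NNC) were matched between libraries by exact junction positions.

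The text draws its named genes from the 10 nuclear genes with the highest mean CPM, the 3 members with the highest mean CPM of every list, up to 10 called genes in each direction, at most 30 cassette events of the list of splice events (per gene the exon with the most reads, and the one at the lower coordinate where reads are equal), the 5 most abundant new chains, the 10 genes with the smallest p for the leading isoform, and the 5 splicing regulators with the highest share of decay or retained intron isoforms. Some genes that these rules pick are not reported here. Other genes are named as chosen after their values were seen.

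The alternatives were pseudocounts of 0.1 and 10 CPM, a minimum of 10 reads for agreement, minimums of 5 and 100 reads for the gene test, trimmed mean of M-values (TMM) scaling, totals without mitochondrially encoded genes, and a negative binomial spread for the gene test. The reads of known transcripts alone, other read minimums, other microexon limits, 1 event per gene and leaving out each library were also tried. edgeR 4.0.16 in R 4.3.3 gave the TMM factors and the common dispersion. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The 2 strains' alleles were not analysed here, since the tables hold no base calls. The SIRV spike-ins were not analysed here, because 0 models carry their names. A genome sequence was not used here; sequences came from the GENCODE M21 transcripts.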

Results

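Full-length RNA reads were collected from the left cerebral cortex of 2 female B6CASTF1/J hybrid mice at 2 months of age, 1 library per animal. The labels name no treatment or second group, so the data answer which genes and isoforms the cortex of these animals expressed and how closely the 2 libraries match. Replicate 1 held 686395 reads in 126865 transcript models and replicate 2 held 858276 reads in 147992 models. Annotated genes took 87.5% of the reads of replicate 1 and 86.9% of those of replicate 2. A read was found for 16011 genes in replicate 1 and 16510 genes in replicate 2, with 14475 genes seen in both. Values are means ± SD over n = 2 animals unless a library is named. Wilson intervals cover counting error only, other intervals reflect the spread over exons, genes or models, and none covers variation between animals.

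Among the 10 most abundant nuclear genes, Ndrg4 had 3200 ± 161 CPM. Cpe, an enzyme that trims neuropeptide precursors, stood at 3181 ± 351 CPM, and the ubiquitin gene Ubb at 3156 ± 23.3 CPM. The lipid carrier Apoe had 2985 ± 212 CPM, and the neuronal gene Ncdn 2853 ± 99.7 CPM. Kif5a, a motor of axonal transport, had 2518 ± 522 CPM, Sparcl1 2290 ± 237 CPM and Aplp1, a relative of the amyloid precursor protein, 2234 ± 21.3 CPM. Mitochondrially encoded genes took 728 CPM in replicate 1 and 820 CPM in replicate 2, with mt-Co1 at 211 ± 10.8 CPM, mt-Rnr2 at 104 ± 4.30 CPM and mt-Cytb at 86.7 ± 11.9 CPM.

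Markers of the cell classes of the cortex were all found. Among excitatory neuron markers the postsynaptic gene Nrgn had 1772 ± 47.6 CPM, the vesicular glutamate transporter Slc17a7 1415 ± 12.9 CPM and Chn1 1329 ± 49.6 CPM. Among inhibitory neuron markers the neuropeptide gene Cck had 500.3 ± 46.2 CPM and the GABA-synthesising enzyme Gad1 471 ± 45.8 CPM. Besides Apoe, the astrocyte list was led by Aldoc at 1682 ± 239 CPM and the glutamate transporter Slc1a3 at 1121 ± 98.3 CPM. Oligodendrocyte markers were led by the myelin protein Mbp at 1394 ± 284 CPM, Cnp at 368 ± 93.9 CPM and the iron carrier Trf at 365 ± 50.1 CPM. The precursor markers Olig1, Pdgfra and Sox10 had 104 ± 17.7, 70.0 ± 2.31 and 46.8 ± 9.64 CPM. Microglial markers included Sparc at 215 ± 20.7 CPM and Csf1r at 192 ± 17.8 CPM, of which Sparc is also known from vessels. Endothelial and mural markers were led by Bsg at 701 ± 14.9 CPM, Slc2a1 at 126 ± 20.3 CPM and Rgs5 at 116 ± 3.07 CPM. The median marker level was 132 ± 4.43 CPM for excitatory neurons, 47.9 ± 5.24 for inhibitory neurons, 235 ± 20.7 for astrocytes, 59.99 ± 11.8 for oligodendrocytes, 39.1 ± 8.19 for their precursors, 47.1 ± 14.8 for microglia and 41.2 ± 9.99 for endothelium and mural cells. These levels are of different genes and were not tested between classes. The reads come from whole cortex, so the level of a listed gene, such as Cck, need not come from that class alone. With known transcripts alone the median was 35.6 CPM for excitatory and 30.8 CPM for inhibitory neuron markers.

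Among synaptic vesicle genes, which serve transmitter release, Snap25 had 2140 ± 39.9 CPM and Vamp2 1738 ± 17.4 CPM. In the postsynaptic density, behind Nrgn, the kinase gene Camk2b had 1032 ± 7.86 CPM and the scaffold gene Dlgap3 617 ± 182 CPM. Glutamate receptor subunits were led by Grin1 at 865 ± 6.11 CPM, Gria2 at 523 ± 46.5 CPM and Gria1 at 311 ± 61.3 CPM. Among GABA receptor subunits Gabbr2 had 447 ± 25.4 CPM. Of the large ion channels, the sodium channel gene Scn8a had 288 ± 13.7 CPM. Among long noncoding RNAs, Meg3 had 656 ± 44.5 CPM, Snhg11 437 ± 52.8 CPM and Miat 327 ± 57.1 CPM.

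The 2 libraries matched closely across genes. Over the 18046 genes with a read in either, r of log2(CPM + 1) was 0.928 and rho was 0.939; genes are not independent replicates, and no p-value is given. In the 1295 genes with at least 100 reads in each library the log2 ratio had an SD of 0.22, against 0.15 from counting error.

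**Figure D1:**
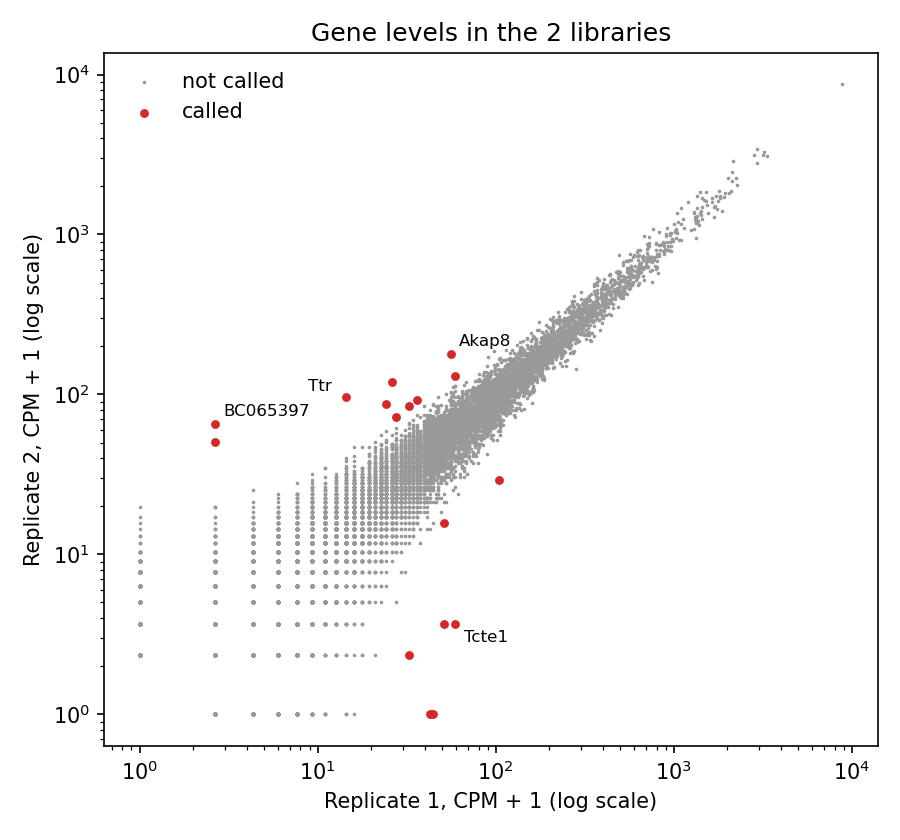
Each point is a gene, placed by its level in replicate 1 (horizontal axis) and replicate 2 (vertical axis), as CPM plus 1 on log scales. Red points are the 17 genes called different by the exact binomial test; most other genes lie along the diagonal.

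Of 9089 genes tested, 17 were called different between the libraries, 10 higher and 7 lower in replicate 2. Ttr, the thyroxine carrier made in abundance by choroid plexus, had 8 reads in replicate 1 and 71 in replicate 2, a log2 ratio of 2.76 (adjusted p = 8.1e-08, exact binomial test). Akap8, which encodes a nuclear anchor of protein kinase A, had 33 and 133 reads, a log2 ratio of 1.68 (adjusted p = 8.1e-08, same test). By the exact binomial test Ap1g2, an adaptor subunit of vesicle transport, was higher with 14 and 64 reads (log2 ratio 1.84, adjusted p = 0.00033), and so was the neuronal repressor gene Scrt1 with 35 and 96 reads (log2 ratio 1.13, adjusted p = 0.00715). P3h3, a collagen-modifying enzyme, and the translation factor subunit Eif3k were also higher, at log2 ratios of 1.37 and 1.38. Lower in replicate 2 were the muscarinic receptor gene Chrm4, with 30 and 11 reads (log2 ratio -1.72, adjusted p = 0.0352, exact binomial test), the testis gene Tcte1 with 35 and 2 reads (log2 ratio -4.14), and the pseudogene Gm37313 with 19 and 1 reads (log2 ratio -4.01). The processed pseudogene Vcp-rs was higher in replicate 2 with 15 and 88 reads. Because Vcp-rs is a copy of Vcp and lies within another gene, the assignment of its reads is uncertain.

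Other called genes share exonic bases with a neighbour on the same strand, and their counts are uncertain. This held for 6 of the 17 called genes (35.3%) and for 795 of 9072 other tested genes (8.76%, two-sided Fisher's exact p = 0.00244). They were BC065397 with 1 and 48 reads, Gm36995 with 1 and 37, Tmc4 with 21 and 68, Gm49450 with 30 and 2, and the protocadherin gene Pcdhga2 and Gm49325 with 26 and 25 reads in replicate 1 and 0 in replicate 2. Against a floor of 3 reads in replicate 2, Pcdhga2 was at least 10.8-fold lower and Gm49325 at least 10.4-fold lower. When overlapping genes were merged into units, an alternative chosen after the data were seen, 11 of 8961 units were called, 7 higher and 4 lower. Of these 6 genes only BC065397 was still called then. Eif3k, which shares no exonic bases with a neighbour, kept its counts. It also lost its call, through the adjustment alone (adjusted p = 0.0565, exact binomial test). With a negative binomial spread between libraries, estimated across genes, 12 genes were called, 6 higher and 6 lower, and Scrt1, Tmc4, P3h3, Eif3k and Chrm4 lost their call. That spread came from these same 2 libraries taken as 1 group. It used 8182 genes, after those with the most extreme log2 ratios were set aside. It is therefore no separate measure of variation between animals, and the 12 calls are not shown to exceed such variation. With the reads of known transcripts alone 7 genes were called, and among genes with at least 100 reads 3 were called.

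At any fold, 38 genes were higher and 29 lower in replicate 2 at an adjusted p under 0.05 in the exact binomial test. Under TMM scaling these were 50 and 25, and with the negative binomial spread 6 and 7. Among the higher genes in the exact binomial test were Kif5a with a log2 ratio of 0.43 (adjusted p = 2.3e-13), Cpe with 0.23 (adjusted p = 1.4e-04) and Sparcl1 with 0.21 (adjusted p = 0.0123). These 3 did not pass with the negative binomial spread (adjusted p = 0.689, 1.0 and 1.0). Of the 50 genes under 2-fold that passed in the exact binomial test, only Gm45837 passed with that spread too. The calls of list members given below, apart from Ttr, therefore exceed counting error only, and adjustment over a list alone was not repeated with that spread. Ttr exceeded that spread too, but was not shown to exceed variation between animals.

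Lists of astrocyte, oligodendrocyte and precursor markers were higher in replicate 2. The astrocyte list had a median log2 ratio of 0.35, above all 10000 random lists drawn, with 15 of 16 tested members above 0. Over all genes tested 2 members were higher, among them the glycolytic enzyme gene Aldoc at a log2 ratio of 0.29 (adjusted p = 0.000713, exact binomial test). Adjusted over the list alone, 11 astrocyte genes were higher, and 0 of them reached a 2-fold difference. The oligodendrocyte list had a median of 0.37 at percentile 99.99, with 11 of 12 members above 0. The myelin genes Mbp, Mobp and Cnp were higher at log2 ratios of 0.42, 0.93 and 0.52, and adjusted over the list alone 4 genes were. The precursor list had a median of 0.41 at percentile 99.04. The microglia list had 0.21 at percentile 96.01, within the central 95% of random lists, with 0 members passing in either list over all genes tested or adjusted over the list alone. Neuronal lists lay below 0 but within the range of random lists, with medians of -0.12 for excitatory markers at percentile 10.4 and -0.19 for inhibitory markers at percentile 3.55, and 0 members passed over all genes or adjusted over the list alone. The endothelial and mural list had a median of 0.01 and a mean of -0.08, and adjusted over the list alone only its member Vtn was lower (log2 ratio -1.13). With known transcripts alone, an alternative chosen after the data were seen, the median of the precursor list was 0.35 and lay within the central 95% of random lists, and that of the microglia list was 0.34 and lay above it.

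Immediate early genes, which are switched on by neuronal activity, were lower in replicate 2. Their median log2 ratio was -0.28 at percentile 0.01, with 3 of 22 tested members above 0. The transcription factor gene Egr4, at 319 ± 93.0 CPM, passed over all genes tested with a log2 ratio of -0.60 (adjusted p = 0.00575, exact binomial test). Adjusted over the list alone, 5 members were lower (Egr4, Egr1, Fos, Junb and Nr4a2, with log2 ratios of -0.60, -0.51, -0.97, -0.44 and -0.67) and 1 was higher, Arc, at 717 ± 108 CPM with a log2 ratio of 0.31. The scaffold gene Homer1, at 474 ± 43.2 CPM, had -0.19 and did not pass. The circadian list had a median of -0.25 at percentile 0.58 and a mean of -0.04, with 4 of 14 members above 0 and 0 passing over all genes or adjusted over the list alone. Its most abundant members, Tef, Cry2 and Hlf, had 487 ± 26.3, 382 ± 34.4 and 104 ± 4.30 CPM.

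Ribosomal protein genes had a median log2 ratio of 0.18 at percentile 99.63, and splicing regulators 0.18 at percentile 99.6. With known transcripts alone the median of the splicing regulators was 0.09, within the central 95% of random lists, over 19 tested members instead of 29. No ribosomal protein gene passed over all genes or adjusted over the list alone; Rpl3, Rpl41 and Rpl4 led the list at 429 ± 2.75, 392 ± 43.9 and 262 ± 33.4 CPM. Of the splicing regulators Qk, a glial RNA-binding protein gene at 660 ± 130.0 CPM, was higher at a log2 ratio of 0.40 (adjusted p = 0.00947, exact binomial test) and was the 1 member higher adjusted over the list alone, while Celf4 and Rbfox3 had 936 ± 48.9 and 705 ± 28.1 CPM and did not pass. The blood list had a median of 0.71 at percentile 99.26 over 3 tested genes, with Hba-a1, Hbb-bs and Hba-a2 at 85.4 ± 38.4, 37.6 ± 13.1 and 28.1 ± 2.00 CPM; the globin copies share much of their sequence, and their split is uncertain. Adjusted over the list alone 1 blood gene, Hba-a1, was higher.

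The remaining lists, apart from choroid plexus, lay within the central 95% of random lists. Among meningeal and fibroblast genes Ptgds, which makes prostaglandin D2, was lower at a log2 ratio of -0.40 (adjusted p = 1.5e-07, exact binomial test) and stood at 1630.1 ± 321 CPM, and the list had a median of -0.27 and a mean of 0.03. Igfbp2 and Col1a1 had 74.0 ± 15.53 and 59.0 ± 3.78 CPM; adjusted over the list alone Ptgds was lower and Dcn higher. The choroid plexus list had 2 tested members, Ttr and Enpp2 (248 ± 22.1 CPM), too few for a percentile, and Kl had 8.02 ± 1.92 CPM; adjusted over the list alone only Ttr was higher. Genes listed for neighbouring regions were low to moderate, and their reads need not come from those regions. Striatal Ppp1r1b and Penk had 280 ± 33.4 and 154 ± 26.8 CPM, with a list median of -0.13. Of the hippocampal list, Wfs1, Amigo2 and Neurod1 had 447 ± 21.9, 24.7 ± 2.73 and 20.2 ± 2.04 CPM, with a list median of -0.06. Thalamic and hypothalamic Calb2, Slc17a6 and Lef1 had 35.4 ± 2.98, 18.8 ± 13.4 and 18.03 ± 2.76 CPM, with a list median of -0.31, and adjusted over the list alone Slc17a6 was lower.

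The synaptic vesicle list had a median of -0.12, with 1 member lower over all genes tested, and adjusted over the list alone 2 were higher and 4 lower. In the postsynaptic density Dlgap3 was higher at 0.61 (adjusted p = 1.6e-06, exact binomial test); the list median was -0.02 and its mean 0.04, and adjusted over the list alone 3 were higher. Glutamate receptors had a median of -0.08 over 19 tested members, with Gria1 and Gria3 lower adjusted over the list alone. With known transcripts alone, where only 9 members were tested, their median was -0.31 and lay under the central 95% of random lists. Genes with known splice events, led by Snap25, Pkm at 1926 ± 156 CPM and App at 1583 ± 146 CPM, had a median of -0.04, with 2 higher and 8 lower adjusted over the list alone. No member passed, over all genes or adjusted over the list alone, among GABA receptors (median -0.13), large ion channels (-0.04, mean -0.01), heat shock genes (-0.05), interferon response genes (-0.18), mitochondrially encoded genes (0.11), nuclear oxidative phosphorylation genes (-0.07) or long noncoding RNAs (0.11, mean -0.01). The chaperones Hspa8, Hsph1 and Hsp90aa1 had 2149 ± 140.1, 588 ± 59.5 and 569 ± 12.6 CPM. The respiratory chain genes Cox4i1, Atp5b and Atp5a1 had 1305 ± 15.97, 1038 ± 19.6 and 862 ± 30.05 CPM. The immune genes H2-D1 and B2m had 55.8 ± 1.19 and 38.1 ± 2.68 CPM. Glucocorticoid response genes had a median of 0.11, with Tsc22d3, Errfi1 and Mt1 at 164 ± 29.5, 156 ± 42.8 and 152 ± 18.8 CPM, and adjusted over the list alone Errfi1 was lower.

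**Figure D2:**
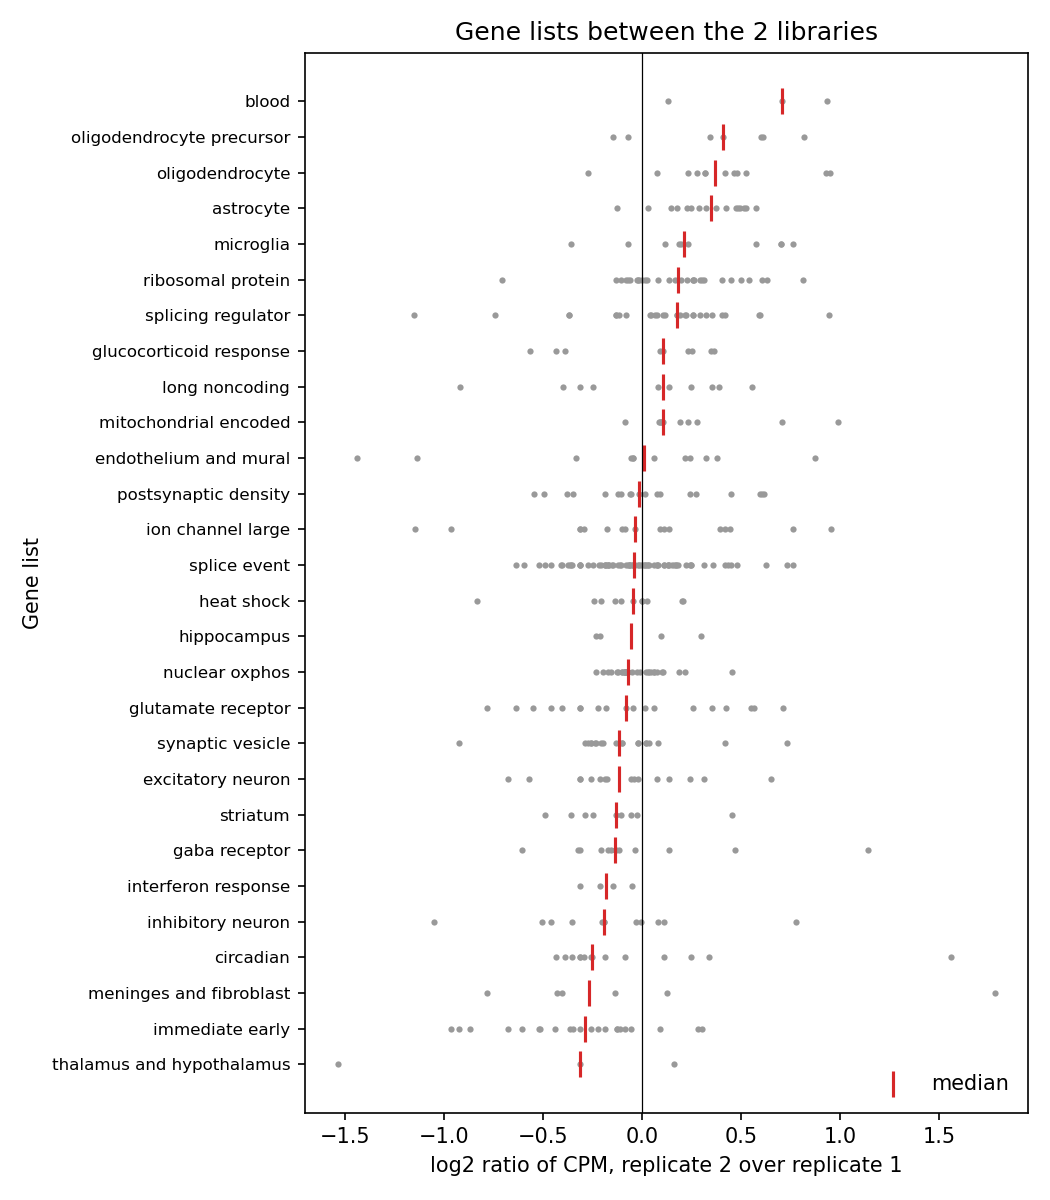
Grey points are the tested genes of each list by their log2 ratio of CPM (replicate 2 over replicate 1), and red bars are list medians. The astrocyte and oligodendrocyte medians lie at 0.35 and 0.37 and the immediate early median at -0.28.

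Known transcripts took 59.2% of the reads of replicate 1 (Wilson 95% interval 59.1 to 59.3) and 58.7% of those of replicate 2 (58.6 to 58.9), spike-ins left out. Incomplete splice matches took 9.84% ± 0.0559, NIC models 9.35% ± 0.328, NNC models 4.83% ± 0.209, antisense models 10.9% ± 0.187, intergenic models 0.872% ± 0.0595 and genomic models 5.28% ± 0.00747. Of the reads in incomplete splice matches, 72.8% in replicate 1 and 72.1% in replicate 2 lacked only the 5' part of the transcript. Antisense models had a single exon in 98.0% and 98.2% of their reads. By Fisher's exact test, two-sided, NIC models took a larger share in replicate 2 (adjusted p = 7.4e-22), as did antisense and intergenic models, and known and NNC models a smaller one; all these differences were under 0.5 percentage points. Without the reads antisense to Gm26917, an alternative chosen after the data were seen, the directions of 2 of these turned. The antisense share was then 7.85% in replicate 1 and 7.07% in replicate 2, and the known share 61.1% and 61.3% (adjusted p = 6.4e-72 and 0.00206, Fisher's exact test), while NIC, intergenic and NNC models kept their direction. The NNC difference did not pass among models with at least 2 reads (p = 0.103) or 5 reads (p = 0.0775, Fisher's exact test, not adjusted). The shares of incomplete splice matches (adjusted p = 0.120) and genomic models (adjusted p = 0.771) did not pass this test. Among models with at least 5 reads, incomplete splice matches took 5.72% in replicate 1 and 5.85% in replicate 2 (p = 0.00172, Fisher's exact test, not adjusted), the other direction from that over all models.

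Among reads of known transcripts, 95.4% ± 0.186 belonged to protein-coding isoforms, 1.48% ± 0.0910 to retained intron isoforms, 0.734% ± 0.00408 to processed transcripts and 0.583% ± 0.0424 to isoforms annotated as targets of nonsense-mediated decay, the pathway that removes transcripts with early stop codons. Of 4038 protein-coding genes with at least 20 known reads in each library, 79 (1.956%) had over 25% of these reads in decay or retained intron isoforms. The splicing factor Srsf1 had 24.8% ± 6.81 of its known reads in such isoforms, Srsf7 23.1% ± 5.29, Srsf11 17.3% ± 3.83, Hnrnpdl 13.4% ± 2.52 and Khdrbs3 13.2% ± 3.93. None of the 14 splicing regulators in this set exceeded 25% in the mean of the libraries, while Srsf1 had 29.6% in replicate 1 and Srsf7 26.8% in replicate 2. Among the other genes, chosen after their values were seen, Cttnbp2 had 93.2% ± 0.489, the splicing kinase gene Clk1 91.8% ± 6.01, Ccnl2 88.5% ± 5.01 and the synapsin gene Syn2 73.9% ± 1.67. Cox4i1 had 67.8% ± 5.54.

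The leading isoform took a median of 72.7% of a gene's spliced reads over 2627 genes with at least 50 such reads in each library. The same intron chain led in both animals in 2470 genes (94.0%), and 1063 genes (40.5%) had at least 2 isoforms with 10% or more each. Every intron chain counts as an isoform here, also one that follows only part of a transcript. The latter share was 38.7% of 2315 genes without incomplete splice matches and 26.0% of 1745 genes with known transcripts alone. The leading chain was known in 2320 genes (88.3%), NIC in 206, an incomplete splice match in 78 and NNC in 23. Among named genes, App-201 took 82.3% ± 0.239 of the spliced reads of the amyloid precursor gene App, Gnas-208 88.2% ± 1.72 of the G protein gene Gnas, Camk2b-209 55.9% ± 2.15 of Camk2b and Mapt-204 47.6% ± 7.63 of the tau gene Mapt.

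The share of the leading isoform differed between the libraries in 3 genes after adjustment (Fisher's exact test, two-sided), and in 178 at an unadjusted p under 0.05. Jph4-201, of a gene that ties surface and endoplasmic membranes, took 36.4% of Jph4 reads in replicate 1 and 57.6% in replicate 2 (adjusted p = 0.00675, Fisher's exact test). Pde4dip-201 took 8.22% and 27.8% of Pde4dip reads (adjusted p = 0.00695, same test). In Gm45837, 131 of 168 reads followed an incomplete splice match in replicate 1 and 0 of 107 in replicate 2. Gm45837 overlaps the phosphodiesterase gene Pde2a on the same strand, and Pde2a had 377 reads in replicate 1 and 597 in replicate 2, so the split of reads between them is uncertain. The next genes by p did not pass. Among them were Adcy5, Ncor1, Abcb9, Cox4i1, Sec14l1 and Tecr, whose leading isoform took 80.4% ± 11.04, 23.8% ± 18.01, 60.5% ± 16.9, 65.9% ± 5.52, 65.1% ± 11.7 and 55.0% ± 10.4. With known transcripts alone 0 genes differed after adjustment and 54 at an unadjusted p under 0.05, and without incomplete splice matches 5 genes did.

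Inclusion of cassette exons in synaptic and cytoskeletal genes was measured from single reads that join both neighbouring exons. Of the genes with known splice events, 53 had such an exon with enough reads. Each gene is described by its exon with the most reads, and other exons of the same gene can differ. By that exon 31 genes lay between 5% and 95% inclusion, 9 above and 13 under. The calcineurin subunit gene Ppp3ca included its 30-nt exon (3, 136932011 to 136932040) in 82.4% ± 1.02 of reads. Grin1, the obligate NMDA receptor subunit, included its 111-nt exon (2, 25294438 to 25294548) in 62.2% ± 1.40. Mbp included a 123-nt exon in 20.96% ± 0.865. The transcription factor gene Mef2d included its 21-nt exon (3, 88161781 to 88161801) in 94.0% ± 1.42. The membrane-shaping gene Bin1 included a 93-nt exon in 87.2% ± 0.252.

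In genes of vesicle coats inclusion of the exon with the most reads was 80.0% ± 2.21 in Ap2a1 (66 nt), 74.6% ± 1.47 in Ap1b1 (21 nt), 79.9% ± 5.42 in the clathrin light chain gene Cltb (54 nt) and 84.2% ± 5.51 in its relative Clta (54 nt). Among adhesion genes inclusion was 60.3% ± 8.96 in Ncam1 (30 nt), 39.7% ± 13.2 in Nrcam (30 nt), 90.7% ± 3.03 in Nfasc (45 nt), 40.04% ± 7.55 in Cadm1 (84 nt), 73.0% ± 7.87 in the myelin gene Mag (45 nt) and 86.2% ± 1.27 in Nrxn3 (90 nt). Among kinases and transport genes it was 71.2% ± 1.94 in Camk2d (42 nt), 31.5% ± 3.12 in Camk2g (114 nt), 40.8% ± 4.33 in the motor gene Kif1a (24 nt) and 43.6% ± 7.75 in Rims1 (72 nt). The mitochondrial fission gene Dnm1l included a 39-nt exon in 48.2% of reads of replicate 1 and 29.5% of replicate 2, a difference that did not pass adjustment (adjusted p = 1.0, Fisher's exact test). In Add1 2 exons had equally many reads, of 87 nt with 20.5% ± 2.91 and of 37 nt with 27.505% ± 1.72. Inclusion was 6.33% ± 0.838 in Tpm3 (79 nt), 54.3% ± 2.23 in Tsc2 (69 nt), 81.0% ± 6.63 in Asph (45 nt), 46.9% ± 4.37 in Map4 (190 nt), 18.7% ± 3.17 in Gphn (108 nt) and 78.9% ± 3.07 in Eif4g1 (57 nt). None of the 4507 cassette exons tested differed between the libraries after adjustment, and 84 had an unadjusted p under 0.05 (Fisher's exact test, two-sided). Across exons rho between the libraries was 0.960.

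**Figure D3:**
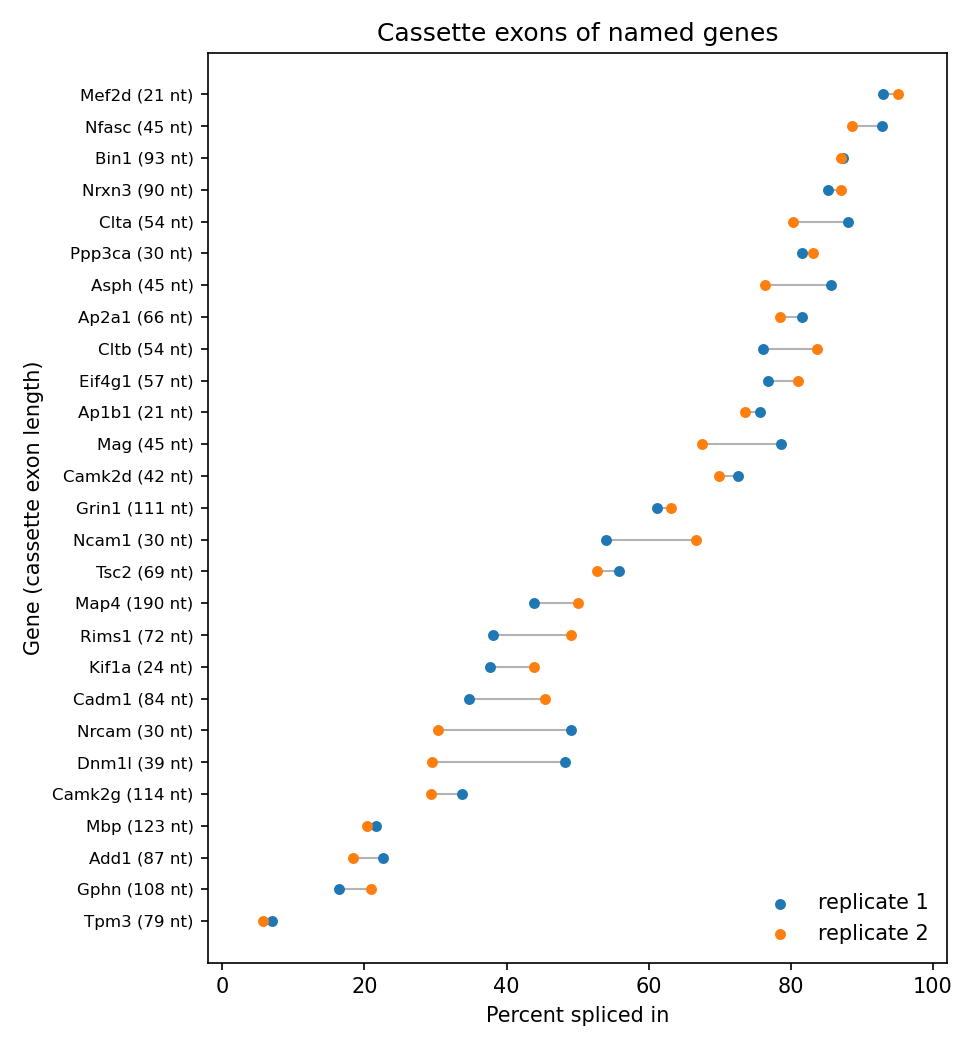
Percent spliced in of cassette exons of named genes, with exon lengths beside the gene names, in replicate 1 (blue) and replicate 2 (orange). The exons shown were taken from those with inclusion between 5% and 95%, and among them it ranged from 6.33% in Tpm3 to 94.0% in Mef2d.

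Pairs of exons that replace each other, chosen for measurement after the data were seen, gave the following shares. Snap25 used its upstream exon (2, 136769743 to 136769860) in 10.6% ± 0.136 of reads. Gria1, an AMPA receptor subunit, used the upstream exon (11, 57309769 to 57309883) in 66.8% ± 0.239. Pkm, the pyruvate kinase gene, used the upstream exon (9, 59675029 to 59675195) in 89.1% of reads of replicate 1 and 83.7% of replicate 2 (two-sided Fisher's exact p = 8.8e-05, not adjusted). Camk2d used the upstream exon of its pair in 85.9% ± 1.93 and Dnm2 in 43.5% ± 10.8.

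Microexons, a class known for neural inclusion, were included less than longer cassette exons in these reads. The 164 exons of 3 to 27 nt had a mean inclusion of 42.4% ± 0.223 and the 4343 longer ones 57.7% ± 0.0162. The difference of -15.3 percentage points (95% bootstrap interval over exons -21.5 to -8.83) had a two-sided permutation p of 3e-05; exons are not independent replicates. It rested on the shortest exons. The 38 cassette exons of 3 to 15 nt had a mean inclusion of 12.4%, and 32 of them had 0 inclusion reads. With exons of 15 nt or less left out, an alternative chosen after the data were seen, 126 microexons had a mean of 51.5% and the difference was -6.23 points (-13.4 to 0.949, permutation p = 0.116).

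Exons of 15 nt were seen at high inclusion in the cytoskeletal genes Abi1 (98.2% ± 2.48) and Sptan1 (98.4% ± 0.0296) and the endocytic gene Snap91 (97.2% ± 1.04), at 58.7% ± 3.20 in Itsn1 and at 46.9% ± 7.59 in Arhgef10l. The shortest included cassette exon, of 12 nt in Dnm2, was at 72.4% ± 5.40. None of the 16 cassette exons under 12 nt had an inclusion read, although 38 models with 68 reads held an internal exon of 11 nt or less. The 3 exons of 3 to 15 nt that no annotated transcript skips and at least 20 reads span in each library, in Cpne9, Pitpnc1 and Supt5, were also absent from all reads that span them. The 6-nt exon of Nsmf (2, 25057965 to 25057970) was absent from 359 reads of replicate 1 and 568 of replicate 2, and that of Apbb1 (7, 105565946 to 105565951) from 66 and 90. These genes were chosen after their values were seen.

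**Figure D4:**
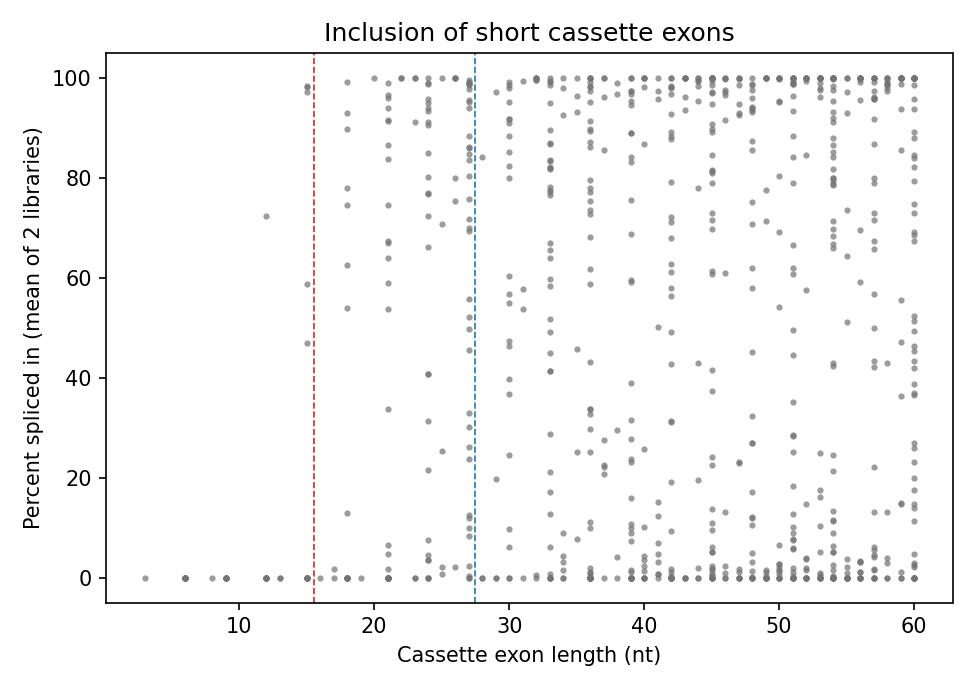
Mean inclusion over both libraries (vertical axis, percent) against length (horizontal axis, nt) for cassette exons of up to 60 nt. Dashed lines stand just above 15 nt and 27 nt; 32 of the 38 exons of 15 nt or less lie at 0.

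Microexons had a length divisible by 3, which would keep a reading frame, more often than longer cassette exons. Coding sequence was not used, so exons outside it are included. A length divisible by 3 was found in 138 of 164 microexons (84.1%, exact 95% interval 77.6 to 89.4) and in 2139 of 4343 longer exons (49.3%, 47.8 to 50.8; two-sided Fisher's exact p = 7.3e-20). Over all cassette exons, lengths divisible by 3 were most frequent at intermediate inclusion, a difference that was not tested. Among 999 exons with inclusion between 10% and 90%, 69.5% had such a length, against 43.5% of 1443 exons under 10% and 46.2% of 2065 exons above 90%.

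Intron chains outside the annotation numbered 49848 in replicate 1 and 60110 in replicate 2, and 14482 occurred in both, which is 29.1% and 24.1%. Of the chains with at least 5 reads in replicate 1, 95.03% had a read in replicate 2. NIC chains of replicate 1 were found in replicate 2 more often (39.3%) than NNC chains (15.9%). Among chains with at least 5 reads in replicate 1 these shares were closer, at 95.8% and 91.2%, and they were not tested. Some genes were carried mainly by such a chain. In Nrgn a chain with 1 splice site outside the annotation took 1000 reads in replicate 1 and 1199 in replicate 2, or 92.3% and 92.4% of the gene. In Oaz1, the antizyme that controls polyamine synthesis, a new combination of annotated sites took 93.7% and 94.1%, and in Pitpna, a lipid transfer gene, a chain with 1 splice site outside the annotation took 89.4% and 90.8%. Apbb1, whose product binds the amyloid precursor protein, had such a combination in 63.6% and 56.8% of its reads, and Aplp2 in 70.5% and 63.3%. In Apbb1 the annotated 6-nt exon given above was absent from the 66 and 90 reads that join its annotated neighbouring exons. The new chain, with 374 and 397 reads, was not counted among these, and whether it lacks the exon was not examined.

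Spike-in reads took 0.693% of replicate 1 and 0.951% of replicate 2. Of the ERCC spike-ins 49 had a read, 12921 reads in total, with lengths from 273 to 1994 nt. Across spike-ins the rho of reads with length was 0.128, and r of log2 reads between the libraries was 0.963 over the 36 seen in both. The input amounts of the spike-ins were not used, so this rho does not measure recovery by length. The longest was also shorter than the median length of 3067 nt over tested genes. SIRV models were not found in the tables, so the planned spread over their isoforms was not computed.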

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

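Of the tests in this part, those of reads on the wrong strand, of ribosomal RNA and of a lower share of neurons were chosen after the result was seen. Some signals lay outside the comparisons of the report, above the 3 reads that a count of 0 allows. Reads antisense to Gm26917 on chromosome 17 (39843013 to 39846245, minus strand) numbered 57461 over both libraries, or 3.14% of the reads outside spike-ins in replicate 1 and 4.24% in replicate 2. Reads antisense to the long noncoding RNA gene Snhg11 numbered 3894, against 240 and 354 reads of the gene itself. Of the spike-ins, ERCC-00009 had 100 reads and ERCC-00116 had 36, all on the minus strand.

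Antisense reads, of which 98.0% and 98.2% had a single exon, made up 10.7% of replicate 1 and 11.01% of replicate 2, and without the Gm26917 locus 7.85% and 7.07%. Reads given the wrong strand at a common rate are argued against as the whole cause: 38.9% of antisense reads outside that locus (95% interval 32.8 to 45.2) lay opposite genes with at least 10 such reads and fewer sense reads, and of 12921 spike-in reads 1.05% were antisense (upper limit 4.83% with spike-ins resampled), all from 2 of 49 spike-ins. Ribosomal RNA read from its own strand would put its sequence on the minus strand at Gm26917, where 0 of 5 searched segments lay, but this stays open: the 2 segments of 18S lay on the plus strand past the locus and 0 inside it, and the 3 of 28S were found in 0 annotated transcripts and tell nothing. Priming at A-rich stretches also stays open, since the 20 nt after the ends of 918 antisense models within annotated exons held 0.246 more A than random positions of the same exons (95% interval 0.226 to 0.265), and may account for part of these reads. Antisense transcription itself was not tested, because the design names no group that would differ in it.

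Lists of astrocyte and oligodendrocyte markers were higher in replicate 2 than in replicate 1, with medians of 0.35 and 0.37. A different recovery of long and short transcripts is argued against: after a correction for transcript length the astrocyte median was 0.347 (SE of the mean 0.0497), and the log2 ratio had a rho of -0.0209 with length over tested genes. A lower share of neurons would raise all other classes alike. The oligodendrocyte and endothelial medians lay 0.361 apart, and the means of these lists were 0.39 and -0.08. The SE of 0.209 is that of the difference of the means over genes, not of the medians. These lists were also picked as the highest and lowest of those compared, so the values cannot decide. The most abundant members were Apoe, Aldoc and Slc1a3 for astrocytes and Mbp, Cnp and Trf for oligodendrocytes, genes that the cortex itself expresses. A lower share of neurons therefore stays open as a candidate explanation, and with 1 library each it cannot be told apart from a difference between the animals.

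Annotated cassette exons of 3 to 15 nt had a mean inclusion of 12.4%, against 51.5% at 16 to 27 nt. If very short exons were passed over when reads were aligned, exons that no annotated transcript skips would be missing too. The 3 such exons with enough reads, in Cpne9, Pitpnc1 and Supt5, were missing from 100% of the reads that span them, and at a minimum of 5 reads per library 9 of 9 were. Of 120 exons of 16 to 27 nt that no annotated transcript skips, a mean of 0.719% of spanning reads lacked the exon. Of the 16 cassette exons under 12 nt, 0 had an inclusion read. Internal exons of 11 nt or less were held by 38 models with 68 reads, but whether these exons are annotated was not examined. Alignment may therefore lower the values of the shortest exons, such as those of Nsmf and Apbb1. True skipping in cortex was not tested because the design names no other tissue.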

How the results depend on the processing

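Of the tests reported here, those with overlapping genes merged, with known transcripts alone for the gene lists, without exons of 15 nt or less, and without the reads antisense to Gm26917 were chosen after the result was seen. Of 68 comparisons of a result with an alternative, single libraries left aside, 22 stayed within their limit (the SD between libraries, 1.5 times a count, or the same side of a test's threshold), 45 moved and 1 weakened. The causes were not tested except where named. The r between libraries was 0.786 and 0.976 at pseudocounts of 0.1 and 10 CPM, 0.945 with at least 10 reads, where fewer genes near 0 enter, and 0.901 with known transcripts alone. The count of 17 differing genes became 7 with known transcripts alone, 3 with at least 100 reads, where fewer genes are tested, and 11 with overlapping genes merged. With known transcripts alone, median marker levels were 35.6 CPM for excitatory neurons, 30.8 for inhibitory neurons, 265 for astrocytes, 73.2 for oligodendrocytes and 28.2 for endothelium and mural cells. Models with at least 2 reads gave shares of 65.9% known, 7.96% ISM, 7.24% NIC, 2.34% NNC, 0.602% intergenic and 5.07% genomic, and models with at least 5 reads 71.9% known, 5.79% ISM, 5.65% NIC, 1.54% NNC, 10.3% antisense, 0.394% intergenic and 4.37% genomic, since single-read models leave these totals. Without the reads antisense to Gm26917, which leave the totals, shares were 61.2% known, 10.2% ISM, 9.71% NIC, 7.46% antisense and 5.48% genomic. The median share of the leading isoform was 98.6% with known transcripts alone, 82.2% without incomplete splice matches, and 68.8% and 76.2% at minimums of 20 and 100 reads; differing genes numbered 0 and 5 under the former pair. The microexon difference weakened to -6.23 points without exons of 15 nt or less and kept its direction and its side of the threshold under the other alternatives (-45.1 to -11.4). The difference in the share of lengths divisible by 3 did so too, under both of its alternatives. New chains in both animals numbered 5556 with at least 2 reads and 1864 with at least 5. Transcripts with more than 1 exon gave 97.1% protein coding, 1.31% retained intron and 0.742% processed transcript, and transcripts with at least 5 reads 96.5%, 0.951% and 0.574%, with 0.443% decay isoforms.

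Each library alone gave a rho of spike-in reads with length between 0.128 and 0.184 and a microexon difference between -15.4 and -15.1. For means of 2 libraries either value lies within 1 SD by construction, so that leaving out a library says nothing about their stability. The tests between the libraries have no value with 1 library left. No paired analysis was possible because there is 1 group. Among the gene lists, 8 lay outside the central 95% of random lists with all reads and 8 with known transcripts alone. Of 27 lists compared, 23 stayed on their side, the precursor and splicing regulator lists came inside, and the microglia and glutamate receptor lists went outside. With known transcripts alone fewer members of many lists were tested, so such lists were compared over different sets of genes. Depth limits how low a gene can be seen: a count of 0 allows up to 4.997 CPM in replicate 1 and 4.02 CPM in replicate 2. Of 18046 genes with a read, 9089 had the 20 reads needed for the gene test.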

Other observations

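Of 22352 antisense loci 8202 had a read in both libraries. After Gm26917 and Snhg11, the leading loci lay opposite the glutamate transporter gene Slc1a2, with 1019 and 1235 reads against 164 and 286 of the gene itself, and opposite the synaptic gene Cplx2, with 876 and 913 reads against 195 and 239. Xist, the RNA that silences an X chromosome in female cells, had 20 reads in replicate 1 and 13 in replicate 2. Models shorter than 10 nt numbered 398 in replicate 1 and 464 in replicate 2, with 1648 and 2935 reads.

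Known chains seen once in replicate 1 had a read in replicate 2 in 53.1% of 4565 cases, and new chains seen once in 17.9% of 39733. Among the leading chains outside the annotation, which were named after their values were seen, Trim44 had 264 and 281 reads, Oaz2 207 and 251, and the septin gene Sept7 194 and 231.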
